A study of Mus musculus with 12 samples.

How the data were processed

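Total RNA of 12 mouse spleens, 4 in each of 3 groups, was labelled with biotin and hybridised to Illumina mouse BeadChips, per the labels' protocols. Each array is 1 animal, so the replicate error is the spread between animals. The groups were sham/saline, CLP/saline (caecal ligation and puncture) and CLP/MSC (the same operation followed by mesenchymal stem cells), and each array was assigned to its group by its title.

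The deposited scanner table holds, for each array and each of 45281 probes, the average bead intensity on a linear scale, which was neither background-subtracted nor normalized between arrays. It also holds a detection p-value per probe and array, per the file headers, which is the share of negative control beads at least as bright as the probe. The authors' processed table holds log2 values of the same arrays that share one distribution across arrays, as quantile normalization gives. Within each array its probes have nearly the same order as the scanner signals (rank correlations from 0.999957 to 1). The background treatment behind it is not given in the sources used here, and 27 of its cells in 18 probes are empty. That table served only as an alternative to the scanner values. The array codes in the column headers place the 12 arrays on 2 BeadChips of 6, with 2 arrays of each group on each chip. A term for the chip therefore leaves every mean difference unchanged and alters only its error.

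Signals were background-corrected, quantile-normalized and set on the log2 scale with neqc of limma 3.58.1 in R 4.3.3. The negative control distribution was inferred from the detection p-values, and the offset was 16. Probes were kept if their detection p was under 0.05 in at least 4 arrays, which left 21821. Gene names came from the Entrez ID of the file for 29168 probes and from its RefSeq accession for 1145, both looked up in a RefSeq gene table of the GRCm38.p6 assembly. The remaining 14968 probes kept the symbol in the file. The assembly was used for names alone. Where several probes of a symbol passed, the one with the highest mean log2 signal over all 12 arrays stood for the gene, which applied to 4383 of the 15474 symbols tested. Of the tested symbols, 10928 were named through the RefSeq table.

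A model with 1 mean per group was fitted to all 12 arrays with limma (lmFit and eBayes, 9 residual and 2.77 prior degrees of freedom). The 3 comparisons were CLP/saline against sham/saline, CLP/MSC against CLP/saline and CLP/MSC against sham/saline. Tests of genes and lists were two-sided, with the Benjamini-Hochberg adjustment and a threshold of 0.05. Permutation p values are not adjusted, and the one for islet genes is one-sided. Differences are log2 fold changes of the first group over the second, given with their standard error (SE). A gene whose probes were undetected on every array of a group has only a bound there. It is given as at least so many fold, from the bright group's mean against the mean of the higher of each array's lowest detected signal and the probe's own. Where arrays of the bright group were themselves undetected, as for Il6, they entered its mean at background values. The bound is then not strict.

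Of 43 gene lists, 42 had at least 5 tested members and were tested against all other genes with camera at a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. Some genes stand in more than 1 list, and Lcn2 is one of them. Named genes were set by a rule: the 5 largest increases and decreases among called genes whose 2 groups of 4 arrays did not overlap, the 3 members with the smallest p of each list that passed, at most 2 of other lists, and always Il6, Il10, Il1b, Tnf, Ccl2, Cxcl1, Cxcl2, Cybb, Nos2 and Ly6g, with the Y-linked genes. Not every gene that the rule names is given in the text. The groups, lists, tests, the rule for named genes and most alternatives were set before the data were examined. Apart from the genes always named, the rule picked its genes from these data.

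The steps were tested on simulated data for 15474 genes, with 50 genes changed at each size. In the simulated comparison of CLP/saline with sham, 8% of genes changed 1.5-fold were recovered, 46% at 2-fold, 90% at 4-fold and 92% at 8-fold. In that of CLP/MSC with CLP/saline the shares were 14%, 48%, 88% and 94%, and in that of CLP/MSC with sham 16%, 50%, 86% and 96%. Of the unchanged genes 2, 9 and 7 were called in the 3 comparisons. The shifted list was called each time and 0 other lists were called. The simulated genes varied independently, so this does not show how often lists of correlated genes are called without a change. Their spread was pooled over the 3 groups, while the median SD of genes was 0.167 in sham, 0.320 in CLP/saline and 0.298 in CLP/MSC spleens. The shares for CLP/MSC with CLP/saline are therefore likely too high.

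Alternatives covered the background correction, the normalization, the detection filter, the choice of probe, the authors' values, array weights, the prior, the samples in the fit, the thresholds, the BeadChip, the animal number as a block, and each array left out in turn. Fits with an exocrine pancreas score, fits without the exocrine probes and fits to 1 BeadChip alone were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Nos2 had no probe past the detection filter, no probe carried the name Ly6g, and neither gene was tested.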

Results

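Gene expression was measured in the spleens of 12 female C57Bl/6J mice on Illumina mouse BeadChips, arrays on which the brightness of each bead-bound probe follows the amount of matching RNA. In the CLP/saline group the caecum was tied off and pierced (caecal ligation and puncture, CLP), an operation that lets gut bacteria leak into the peritoneum and is used as a model of sepsis. Saline was infused into the jugular vein 6 hours later. The CLP/MSC mice had the same operation and received cultured male mesenchymal stem cells (MSCs) in place of saline. In the sham/saline group the caecum was brought out and handled, but neither tied nor pierced. Each group had 4 mice, and spleens were taken at 28 hours. The stated aim was to find the RNA changes that accompany the lower inflammation of septic mice given MSCs.

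Each array detected 19457 to 21362 of its 45281 probes (43.0% to 47.2%). Median raw intensities lay between 97.2 and 123, and the brightest probe of an array read between 52259 and 60906. Within a group, arrays correlated across probes at 0.904 to 0.994. The number of arrays, 4 per group, limits the precision. With 4 arrays against 4, an exact two-sided permutation test of a single value cannot give a p below 0.0286.

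Genes of the exocrine pancreas, an organ that lies beside the spleen, varied widely between spleens. The 28 tested genes of this list had array means from 5.35 to 14.86 on the log2 scale. Rnase1, a secreted pancreatic ribonuclease, reached a log2 signal of 15.70 and was undetected in 3 spleens. In sham spleens the list mean was 8.68 and 14.86 in replicates 1 and 3 on BeadChip 1, and 10.38 and 14.80 in replicates 4 and 5 on BeadChip 2. CLP/saline replicates 2 and 3 on BeadChip 1 had 14.53 and 13.64, and replicates 8 and 10 on BeadChip 2 had 5.85 and 8.51. CLP/MSC replicates 4 and 5 on BeadChip 1 had 13.39 and 14.07, and replicates 7 and 8 on BeadChip 2 had 5.35 and 5.47.

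**Figure D1:**
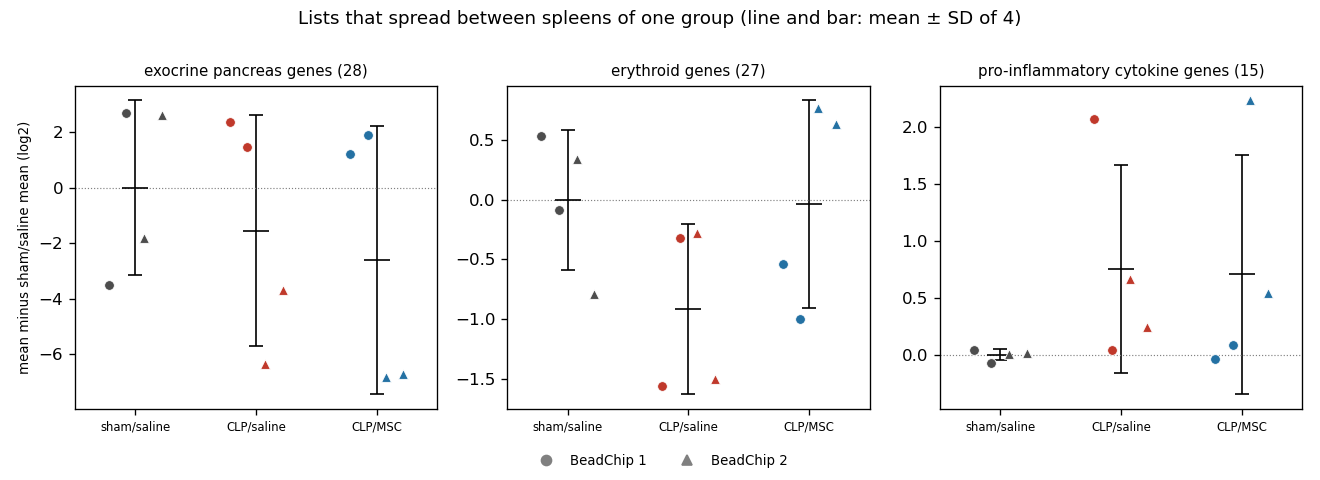
Mean log2 signal of the exocrine pancreas, erythroid and pro-inflammatory cytokine lists in each spleen, minus the sham/saline mean (log2 units), by group. Circles are arrays of BeadChip 1 and triangles of BeadChip 2, and the line and bar give the mean ± SD of 4 arrays. In the CLP groups the exocrine mean was above 0 on BeadChip 1 and below 0 on BeadChip 2, while the cytokine mean reached 2.07 in 1 CLP/saline spleen and 2.23 in 1 CLP/MSC spleen.

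The first comparison, CLP/saline against sham/saline, asked what sepsis changed in the spleen. Acute phase genes rose steeply. Lcn2, whose protein lipocalin 2 binds bacterial siderophores, rose 50.2-fold (log2 5.65 ± 0.24 SE, adjusted p = 2.33e-07), from 8.70 ± 0.25 to 14.35 ± 0.41 (mean log2 signal ± SD, n = 4). Saa3, an acute phase serum amyloid, rose by 6.36 ± 0.48 (adjusted p = 2.62e-05), and the neutrophil-attracting chemokine Cxcl1 by 6.37 ± 1.35 (adjusted p = 0.0128). Markers of natural killer (NK) cells (12 of 16 lower), B cells (11 of 24), T cells (10 of 26) and dendritic cells (7 of 15) were lower as lists. With an estimated correlation between genes these list calls were lost (adjusted p = 0.0570, 0.471, 0.459 and 0.181). Every called gene named for this comparison, apart from Gata1 and Pcna, had all 4 CLP/saline arrays on one side of all 4 sham arrays. So had 2082 of all 2255 called genes, and the largest changes were named only on that condition.

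In all, 2255 of 15474 genes changed, 1218 higher and 1037 lower, and 972 of them by at least 2-fold, 486 each way. Among all tested genes, 3740 (24.2%) had groups that did not overlap, where chance gives 2.86%. Median scaling in place of quantile normalization called 2088 genes with 78.6% of them higher, against 54.0% here. With the chip as a block 2873 genes were called. Across all tested genes, which are not independent replicates, the effects on BeadChip 1 and on BeadChip 2 correlated at 0.605. With the exocrine pancreas mean as a covariate 2667 genes were called, and 2295 with the exocrine probes left out. The count was 974, 1027, 1054 and 1027 without sham replicate 1, 3, 4 and 5, and 879, 4312 and 931 without CLP/saline replicate 2, 3 and 8.

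Among the largest increases were also Cxcl2 and AA467197. Cxcl2, another neutrophil chemokine, was undetected in every sham spleen and at least 40.6-fold higher after CLP (adjusted p = 0.0402). Its call was lost without any 1 sham array, and without CLP/saline replicate 2, 8 or 10 (adjusted p from 0.0684 to 0.119). The limit was 21.8-fold, 120-fold and 25.8-fold without CLP/saline replicate 2, 3 and 8. AA467197 rose by 5.34 ± 0.99 (adjusted p = 0.00699). The largest decreases were those of Gm8221, which fell by 4.71 (SE 0.33, adjusted p = 1.33e-05), Apol7c, which fell by 3.79 (SE 0.38), Fcer2a, Clec4g and Clec9a. Fcer2a, the low-affinity IgE receptor of B cells, fell by 3.60 (SE 0.63, adjusted p = 0.00519). Clec9a, a receptor of cross-presenting dendritic cells, fell by 2.89 (SE 0.46, adjusted p = 0.00337; another detected probe -1.90). Clec4g, a lectin of sinusoidal endothelium, fell by 3.12 (SE 0.81, adjusted p = 0.0279). Its call was lost without any 1 sham array or CLP/saline replicate 2 or 8 (adjusted p from 0.05998 to 0.0806).

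Of the 42 gene lists, 15 passed camera, 7 higher and 8 lower. Both the acute phase and the glucocorticoid response lists also passed with an estimated correlation between genes. With fry 10 of the 15 passed, and the chemokine, immediate-early, cell cycle, oxidative phosphorylation and erythroid lists did not (adjusted p = 0.0558, 0.0917, 0.286, 0.0558 and 0.179). The bacterial killing, glycolysis, iron handling and endothelial lists passed with fry alone (adjusted p = 0.00653, 0.00982, 0.000366 and 0.0271). In the acute phase list 10 of 18 members rose and 0 fell (14 adjusted over the list alone), with a mean change of 2.34 (2.20 on BeadChip 1, 2.48 on BeadChip 2) and an adjusted p of 5.30e-10. With an estimated correlation its adjusted p was 0.0338. Serpina3n, a serine protease inhibitor, rose by 3.94 ± 0.17 (adjusted p = 2.33e-07). Of 19 glucocorticoid response genes 14 rose and 0 fell (16 adjusted over the list alone), with a mean change of 1.76 (1.55 and 1.96 by chip) and an adjusted p of 2.55e-10. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 2.03 ± 0.27 and Angptl4, an inhibitor of lipoprotein lipase, by 1.80 ± 0.25.

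Neutrophil markers rose as a list, with 9 of 22 members higher and 0 lower (12 adjusted over the list alone). Their mean change was 1.37 (1.39 and 1.35 by chip; adjusted p = 1.59e-06), and the adjusted p was 0.328 with an estimated correlation. Fpr2, a receptor for formylated bacterial peptides, rose by 3.06 ± 0.25 and the chitinase-like Chil1 by 3.98 ± 0.45. Among anti-inflammatory regulators 9 of 21 rose and 0 fell (13 adjusted over the list alone; mean 1.54, 1.47 and 1.61 by chip; adjusted p = 5.61e-06, and adjusted p = 0.459 with an estimated correlation). The decoy receptor Il1r2 rose by 4.40 ± 0.38, the signalling inhibitor Socs3 by 4.05 ± 0.52 and the interleukin 18 antagonist Il18bp by 1.05 ± 0.18. The anti-inflammatory cytokine Il10 rose by 4.24 ± 0.75 (adjusted p = 0.00599) and was detected in 2 of 4 sham and 4 of 4 CLP/saline spleens.

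Of 21 chemokines 9 rose and 2 fell (13 and 3 adjusted over the list alone), with a mean of 1.70 (1.51 and 1.89 by chip; adjusted p = 0.00407). With an estimated correlation the adjusted p was 0.510, and it was 0.0558 with fry. Ccl9 rose by 2.01 ± 0.33, Cxcl12 by 1.38 ± 0.11 (other detected probes 0.27 and -0.16) and the B cell chemokine Cxcl13 by 1.37 ± 0.22. Immediate-early genes had 4 of 17 members higher and 0 lower (6 and 1 adjusted over the list alone; mean 0.89, 0.95 and 0.84 by chip; adjusted p = 0.0102, and adjusted p = 0.510 with an estimated correlation). Ier3 rose by 3.21 ± 0.71. Dusp1 and Myc rose by 2.42 ± 0.58 and 1.30 ± 0.32, calls that were lost without CLP/saline replicate 2 or 8 or sham replicate 1 or 5, with sham replicate 4 for Dusp1 and 3 for Myc (adjusted p from 0.0506 to 0.0661). Toll-like receptor and NF-kB genes had 9 of 36 members higher and 1 lower (13 and 1 adjusted over the list alone; mean 0.48, 0.51 and 0.44 by chip; adjusted p = 0.0287). That list's adjusted p was 0.495 with an estimated correlation and 0.0562 without sham replicate 4. Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 3.84 ± 0.71, Bcl3 by 1.44 ± 0.25 and the adaptor Tirap by 0.81 ± 0.15 (other detected probes 0.67 and 0.53). Bacterial killing genes did not pass as a list (7 of 25 higher and 1 lower, 8 and 2 adjusted over the list alone; mean 0.58, 0.52 and 0.64 by chip; adjusted p = 0.0801).

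The pro-inflammatory cytokine list did not pass (mean 0.76, 1.07 and 0.44 by chip; adjusted p = 0.299), with 2 of 15 members higher and 3 lower (3 and 3 adjusted over the list alone). Il18 rose by 0.99 ± 0.12 (adjusted p = 0.000713; another detected probe 0.10), while lymphotoxin alpha, Lta, fell by 1.64 (SE 0.24, adjusted p = 0.00206). Il6 was undetected in every sham spleen and detected in 3 of 4 CLP/saline spleens, at least 5.54-fold higher, without passing the test (adjusted p = 0.223). Its log2 signal was 12.46, 8.98 and 5.80 in CLP/saline replicates 2, 8 and 10, and it was undetected in replicate 3. That spleen entered the mean at a background value, so 5.54-fold is not a strict limit. The limit was 2.004-fold, 11.2-fold and 9.34-fold without replicate 2, 3 and 10. The differences for Il1b (2.05 ± 0.93, adjusted p = 0.147), Tnf (0.76 ± 0.73, adjusted p = 0.489) and Ccl2 (at least 8.003-fold, adjusted p = 0.0979) did not pass either. Nor did that of Cybb, the catalytic subunit of the phagocyte oxidase (0.88 ± 0.50, adjusted p = 0.233). Without CLP/saline replicate 2 these differences were 1.28 for Il1b, 0.06 for Tnf and 0.39 for Cybb, and that of Ccl2 at least 3.61-fold (15.6-fold without replicate 3).

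**Figure D2:**
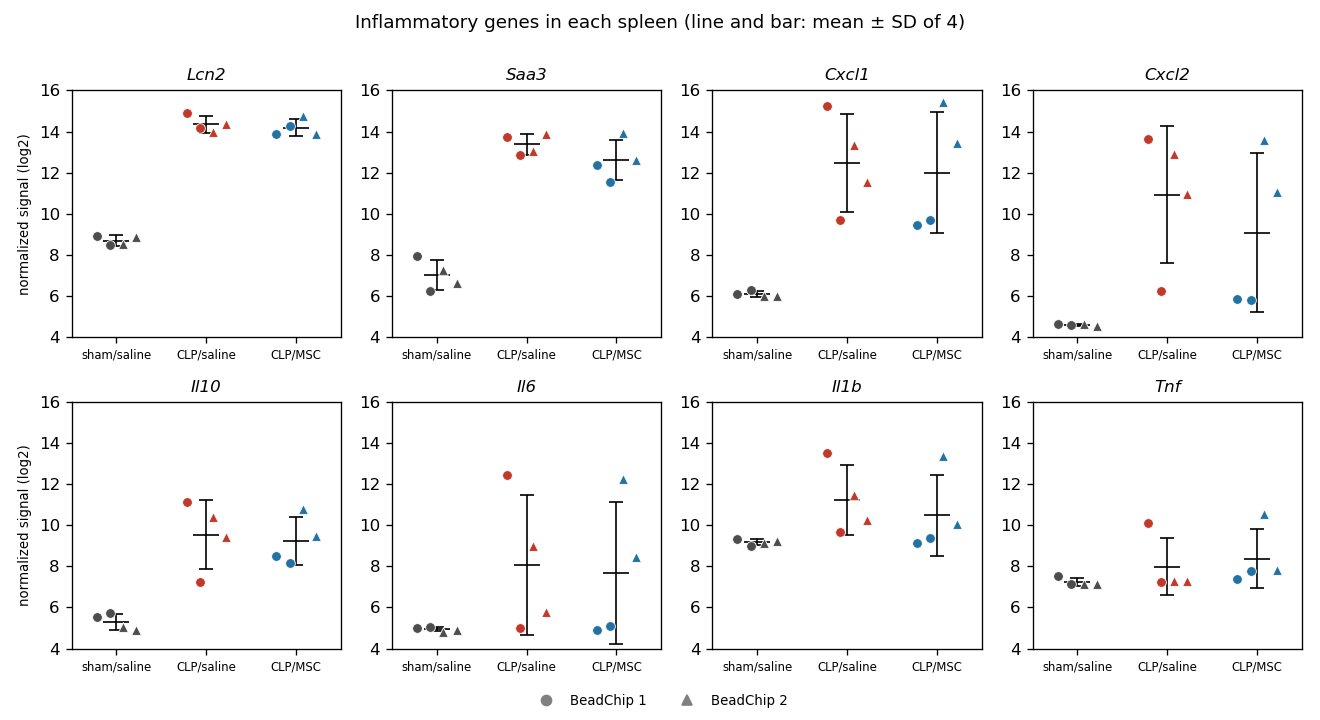
Normalized log2 signal of 8 inflammatory genes in each spleen by group. Circles are arrays of BeadChip 1, triangles those of BeadChip 2, and the line and bar give the mean ± SD of 4. Lcn2 and Saa3 lay above all sham arrays in every CLP spleen, while Il6 reached 12.46 in 1 CLP/saline and 12.23 in 1 CLP/MSC spleen and was undetected in 1 and 2 others.

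NK cell markers had 12 of 16 members lower and 0 higher (12 adjusted over the list alone), with a mean of -1.28 (-1.14 and -1.42 by chip; adjusted p = 3.09e-08, and adjusted p = 0.0570 with an estimated correlation). The NK receptor Klra1 was undetected after CLP, at least 3.12-fold lower, Klra7 fell by 1.69 (SE 0.25) and the chemokine Xcl1 fell by 2.02 (SE 0.26). B cell markers had 11 of 24 members lower and 1 higher (20 and 1 adjusted over the list alone), with a mean of -1.05 (-0.93 and -1.16 by chip; adjusted p = 1.72e-07, and adjusted p = 0.471 with an estimated correlation). Cd1d1, which presents lipid antigens, fell by 1.26 (SE 0.16). T cell markers had 10 of 26 members lower and 1 higher (16 and 2 adjusted over the list alone), with a mean of -0.67 (-0.73 and -0.62 by chip; adjusted p = 1.01e-05, and adjusted p = 0.459 with an estimated correlation). Cd247 and Cd3d, chains of the T cell receptor complex, had log2 changes of -1.20 ± 0.20 (another detected probe -0.67) and -1.13 ± 0.22, and the adhesion molecule Cd2 one of -0.98 ± 0.19.

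Of 15 MHC class II presentation genes 10 fell and 0 rose (10 and 1 adjusted over the list alone; mean -0.74, -0.75 and -0.72 by chip; adjusted p = 0.000395, and adjusted p = 0.304 with an estimated correlation). H2-Aa, a class II chain, fell by 0.72 (SE 0.12), and H2-Oa and H2-DMb2, which regulate peptide loading, had log2 changes of -1.27 ± 0.23 and -1.52 ± 0.30. Of 15 dendritic cell markers 7 fell and 0 rose (7 and 1 adjusted over the list alone; mean -0.82, -0.84 and -0.81 by chip; adjusted p = 0.000612, and adjusted p = 0.181 with an estimated correlation). Cd209a and the chemokine receptor Xcr1 were undetected after CLP, at least 2.17-fold and 1.89-fold lower, and Clec4a4 fell by 2.18 (SE 0.19).

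Erythroid genes were lower as a list, although only 2 of 27 members fell (2 adjusted over the list alone; mean -0.91, -1.16 and -0.67 by chip; adjusted p = 0.00170). Their adjusted p was 0.596 with an estimated correlation and 0.179 with fry. Uros, a haem synthesis enzyme, fell by 2.22 (SE 0.56; other probes -2.03 and -1.10) and the erythroid transcription factor Gata1 fell by 1.12 (SE 0.29), while Alas2 did not pass (-1.86 ± 0.69, adjusted p = 0.0844). Both calls were lost without sham replicate 1, 3 or 4 or CLP/saline replicate 2, 8 or 10 (adjusted p from 0.0512 to 0.0889). Cell cycle genes had 1 of 35 members lower (0 adjusted over the list alone; mean -0.44, -0.46 and -0.43 by chip; adjusted p = 0.00746, and adjusted p = 0.675 with an estimated correlation). The list did not pass without sham replicate 1 or 4 or CLP/saline replicate 10 (adjusted p 0.0539, 0.0735 and 0.0956), and without sham replicate 5 its mean was -0.68. The replication clamp Pcna fell by 0.73 (SE 0.21, adjusted p = 0.0413), a call lost without any 1 sham array or CLP/saline replicate 2, 8 or 10 (adjusted p from 0.0661 to 0.120), while Tyms (-0.96 ± 0.30, adjusted p = 0.0516) and Ccne2 (-1.16 ± 0.43, adjusted p = 0.0860) did not pass.

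Oxidative phosphorylation genes were lower by little, with 2 of 37 members lower (0 adjusted over the list alone; mean -0.19, -0.20 and -0.18 by chip; adjusted p = 0.00901). The adjusted p was 0.510 with an estimated correlation, 0.0554 without sham replicate 4 and 0.129 with median scaling. Cox6b1 fell by 0.42 (SE 0.12) and Ndufa9 fell by 0.77 (SE 0.22), and both calls were lost without any 1 sham array or CLP/saline replicate 2 or 8 (adjusted p from 0.0526 to 0.109). Ndufb9 did not pass (-0.51 ± 0.17, adjusted p = 0.0654). The exocrine pancreas list did not pass (mean -1.55, 2.31 and -5.42 by chip; adjusted p = 0.187).

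**Figure D3:**
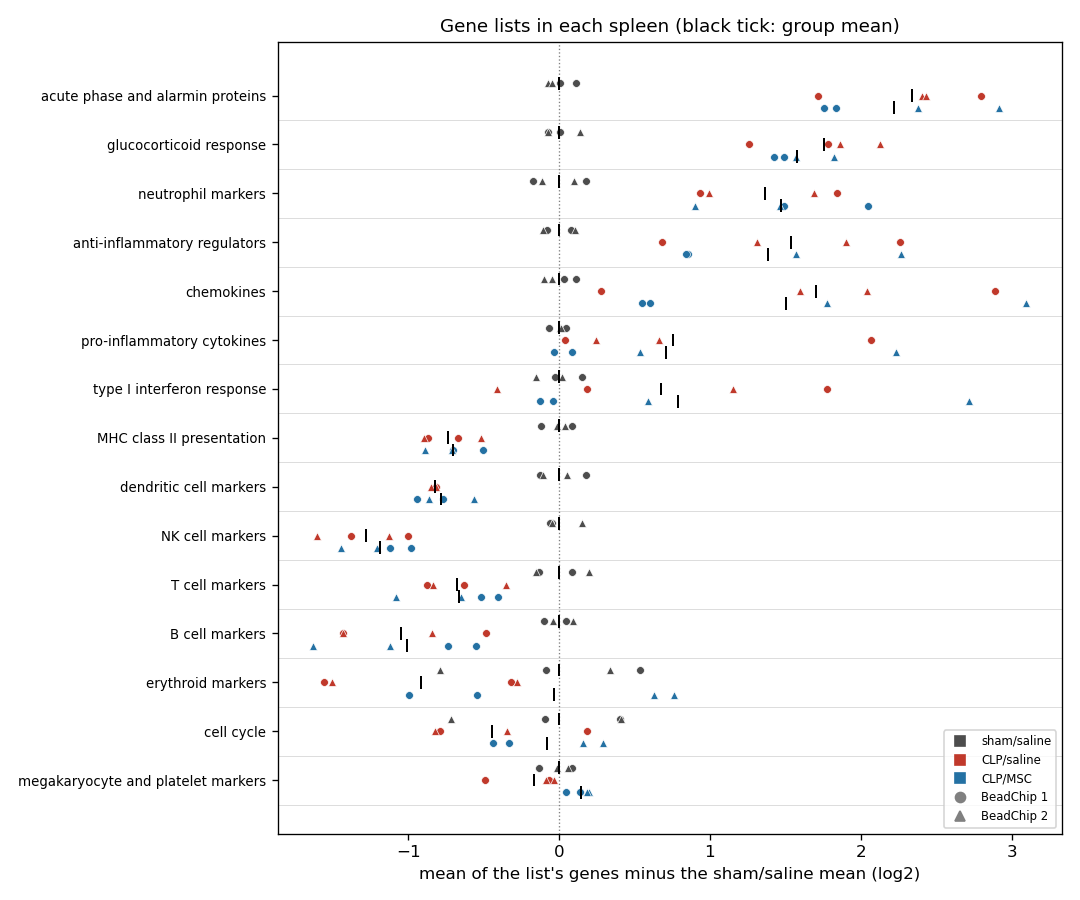
Mean of the genes of 15 lists in each spleen, minus the sham/saline mean (log2 units). Circles are arrays of BeadChip 1, triangles of BeadChip 2, colours mark the groups and black ticks the group means. Acute phase genes averaged 2.34 above sham in CLP/saline and 2.22 in CLP/MSC spleens, and NK cell markers -1.28 and -1.19.

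The second comparison, CLP/MSC against CLP/saline, asked what MSCs changed in septic spleens. No single gene passed the test, the inflammatory genes included. Camera with its preset correlation called the erythroid, megakaryocyte and platelet, cell cycle and MHC class I lists higher in the MSC group. With an estimated correlation none of these calls held (adjusted p = 0.999, 0.591, 0.999 and 0.999), and fry called 0 lists. All 27 erythroid genes had a mean difference above 0, with a list mean of 0.88 (exact two-sided permutation p = 0.171). Uros differed by 1.41 ± 0.56 (other probes 1.41 and 0.08), Gata1 by 0.84 ± 0.29 and Add2, which encodes a red cell membrane protein, by 1.07 ± 0.53.

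limma called 0 of 15474 genes, with a lowest adjusted p of 1.00. At an unadjusted p under 0.05 there were 613 genes, where chance alone gives 773.7, and 203 genes (1.31%) had groups that did not overlap, where chance gives 2.86%. The count was also 0 with array weights (4077 genes at an unadjusted p under 0.05), with the chip as a block, with the exocrine covariate and on each BeadChip alone. Across all tested genes the differences on BeadChip 1 and on BeadChip 2 correlated at -0.271.

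Camera called 4 of 42 lists, all higher, while an estimated correlation and fry each called 0. The list count was 9, 7 and 8 without CLP/saline replicate 2, CLP/MSC replicate 4 and CLP/MSC replicate 7. It was 7 with array weights, 8 on BeadChip 1 alone and 9 on BeadChip 2 alone. The erythroid list had an adjusted p of 6.53e-12, and an adjusted p of 0.999 with an estimated correlation. Its mean difference was 0.17 on BeadChip 1 and 1.59 on BeadChip 2, with an adjusted p of 4.70e-11 with the chip as a block, 0.610 on BeadChip 1 alone and 0.157 with array weights. An exact two-sided permutation test of the list mean over the 70 labellings of the 8 spleens gave p = 0.171. These labellings were not kept within chips. In CLP/MSC spleens the exocrine pancreas list was on average -1.06 relative to CLP/saline (-0.35 and -1.76 by chip), which did not pass (adjusted p = 0.376).

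Of 19 megakaryocyte and platelet genes 16 were above 0 (mean 0.31, 0.37 and 0.25 by chip; adjusted p = 5.31e-07, and adjusted p = 0.591 with an estimated correlation). Without CLP/saline replicate 2 that mean was 0.20. The transcription factor Nfe2 differed by 1.06 ± 0.40 and the platelet tubulin Tubb1 by 0.81 ± 0.26 (another probe 0.04). Of 35 cell cycle genes 31 were above 0 (mean 0.36, -0.08 and 0.81 by chip; adjusted p = 1.13e-05, and adjusted p = 0.999 with an estimated correlation). That list did not pass without CLP/saline replicate 10 (mean 0.24, adjusted p = 0.0526) or with array weights (adjusted p = 0.154), and its mean was 0.57 without CLP/saline replicate 3 and 0.24 without CLP/MSC replicate 8. The mitotic kinase Aurkb differed by 0.64 ± 0.34, E2f1 by 0.48 ± 0.24 and Ube2c, detected in 2 of 4 CLP/MSC and 1 of 4 CLP/saline spleens, by 0.78 ± 0.42. Of 17 MHC class I presentation genes 15 were above 0 (mean 0.18, 0.02 and 0.34 by chip; adjusted p = 0.0102, and adjusted p = 0.999 with an estimated correlation). That list did not pass without CLP/saline replicate 3 or CLP/MSC replicate 7 (means 0.16 and 0.03, adjusted p 0.149 and 0.673), nor with array weights (adjusted p = 0.838). Tapbpl differed by 0.50 ± 0.18 (another probe 0.04), Tap2 by 0.20 ± 0.15 and H2-D1 by 0.26 ± 0.18. In each of the 4 lists 0 members passed, over all genes and adjusted over the list alone.

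Inflammatory genes did not differ detectably at this number of arrays. Il6 was detected in 2 of 4 CLP/MSC and 3 of 4 CLP/saline spleens, so its difference of -0.39 (95% interval -4.18 to 3.40) rests in part on background values. The difference was -0.32 for Il10 (95% interval -1.97 to 1.32), -0.74 for Il1b (-2.78 to 1.30) and 0.39 for Tnf (-1.21 to 1.98), and all 4 had an adjusted p of 1. It was -0.26 ± 1.45 for Ccl2, -0.46 ± 1.35 for Cxcl1, -1.85 ± 1.82 for Cxcl2, -0.40 ± 0.50 for Cybb and -0.77 ± 0.48 for Saa3. Leaving out 1 spleen gave from -1.91 to 1.08 for Il6, -1.09 to 0.20 for Il10, -1.70 to 0.03 for Il1b, -0.33 to 1.09 for Tnf, -1.69 to 0.88 for Ccl2, -1.60 to 0.47 for Cxcl1, -3.41 to -0.77 for Cxcl2, -0.80 to 0.08 for Cybb and -1.21 to -0.41 for Saa3. The lowest values came without CLP/MSC replicate 7 (CLP/saline replicate 3 for Il10 and Cxcl2) and the highest without CLP/saline replicate 2 (CLP/MSC replicate 5 for Cxcl2 and Saa3). The sign also turned without CLP/MSC replicate 4 or 5 for Il6 (0.54 and 0.47), Ccl2 (0.49 and 0.51) and Cxcl1 (0.39 and 0.31), and without replicate 5 for Il10 (0.04). The pro-inflammatory cytokine list had a mean of -0.05 and a median of 0.03 (adjusted p = 0.954), with -1.03 on BeadChip 1 and 0.93 on BeadChip 2. For chemokines the mean was -0.19 (-1.01 and 0.62 by chip; adjusted p = 0.954). The mesothelial list passed with the chip as a block (adjusted p = 0.0139) but not without it (mean -0.58, -0.37 and -0.79 by chip; adjusted p = 0.0778, and adjusted p = 0.999 with an estimated correlation). Markers of mesenchymal stromal cells had a mean of 0.09 (0.18 and 0.01 by chip; adjusted p = 0.392).

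The infused cells were male and the mice female, so Y-linked genes were read in each group. Of 15 probes for 8 such genes, 13 were detected on no array, among them both probes of Eif2s3y and the probe of Kdm5d. A probe of Ddx3y was detected on all 12 arrays, including those of sham mice that received no cells, with raw signals of 730 ± 165 in sham, 1073 ± 231 in CLP/saline and 872 ± 83.7 in CLP/MSC spleens (mean ± SD, n = 4). Whether this probe also binds other RNA, for example that of the X-linked Ddx3x, was not tested, so these signals are no evidence of male cells. A probe of Uty was detected on 2, 4 and 3 of 4 arrays of sham, CLP/saline and CLP/MSC spleens.

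The third comparison, CLP/MSC against sham/saline, asked what remained changed in septic mice given MSCs. Acute phase (10 of 18 higher) and glucocorticoid response genes (9 of 19) were higher and NK cell markers (9 of 16) lower than in sham as lists, also with an estimated correlation. The neutrophil (9 of 22 higher), B cell (7 of 24 lower), T cell (7 of 26) and dendritic cell lists (7 of 15) were called with the preset correlation and with fry. With an estimated correlation they were not called (adjusted p = 0.192, 0.292, 0.279 and 0.119). Lcn2 rose 44.96-fold (log2 5.49 ± 0.24, adjusted p = 3.25e-07), to 14.19 ± 0.41 from 8.70 ± 0.25 (n = 4). Saa3 rose by 5.59 ± 0.48 (adjusted p = 4.95e-05). Fcer2a fell by 3.38 (SE 0.63) and the NK receptor Klri1 was undetected in CLP/MSC spleens, at least 5.42-fold lower (adjusted p = 1.55e-05). Every called gene named for this comparison had all 4 CLP/MSC arrays on one side of all 4 sham arrays. So had 1212 of all 1231 called genes, and the largest changes were named only on that condition.

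Of 15474 genes, 1231 changed, 639 higher and 592 lower, and 573 by at least 2-fold, 291 higher and 282 lower. Groups did not overlap for 3693 genes (23.9%, where chance gives 2.86%). Median scaling called 1048 genes, 74.3% of them higher against 51.9% here. With the chip as a block 1491 genes were called, and across all tested genes the effects on both chips correlated at 0.313. With the exocrine mean as a covariate 1088 were called, and 770 with both. The count was 523, 558, 594 and 555 without sham replicate 1, 3, 4 and 5, and 674 and 629 without CLP/MSC replicate 7 and 8.

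The largest increases included Cxcl1 (5.91 ± 1.35, adjusted p = 0.0230), LOC100048556 (4.98 ± 0.52, adjusted p = 0.000189) and AA467197 (4.52 ± 0.99, adjusted p = 0.0191). Cxcl1 was not called without any 1 sham array or CLP/MSC replicate 7 or 8 (adjusted p from 0.0517 to 0.0689), nor AA467197 without sham replicate 3, 4 or 5 or CLP/MSC replicate 8 (adjusted p from 0.0520 to 0.0577). Gm8221 fell by 4.198 (SE 0.33), Apol7c fell by 2.94 (SE 0.38) and Clec4g fell by 3.26 (SE 0.81, adjusted p = 0.0322). The call for Clec4g was lost without any 1 sham array or CLP/MSC replicate 7 or 8 (adjusted p from 0.0688 to 0.0883). Il10 rose by 3.92 ± 0.75 (adjusted p = 0.0103). Il6 (at least 4.23-fold, detected in 2 of 4 CLP/MSC spleens, adjusted p = 0.336), Cxcl2 (at least 11.2-fold, adjusted p = 0.147), Ccl2 (at least 6.67-fold, adjusted p = 0.157), Il1b (1.30 ± 0.93, adjusted p = 0.396), Tnf (1.15 ± 0.73, adjusted p = 0.338) and Cybb (0.48 ± 0.50, adjusted p = 0.571) did not pass. Without CLP/MSC replicate 7 the limits were 1.47-fold for Il6, 3.97-fold for Cxcl2 and 2.49-fold for Ccl2, and the differences 0.34 for Il1b, 0.43 for Tnf and 0.07 for Cybb. Without replicate 4 and 5 the limits were 8.04-fold and 7.69-fold for Il6, 23.6-fold and 23.9-fold for Cxcl2, and 11.3-fold and 11.4-fold for Ccl2. For Cxcl2 the limit was 7.13-fold without replicate 8, and for Cybb the difference was 0.79 without replicate 5. The Il6 limits are not strict, since replicates 4 and 5, where it was undetected, entered its mean at background values.

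Of the 42 lists 20 passed, 12 higher and 8 lower. With an estimated correlation 3 passed, namely acute phase (adjusted p = 0.0264), glucocorticoid response (adjusted p = 0.0311) and NK cell markers (adjusted p = 0.0473). With fry 16 of the 20 passed, and the chemokine, type I interferon, immediate-early and exocrine pancreas lists did not (adjusted p = 0.0558, 0.478, 0.145 and 0.479). The coagulation and fibrinolysis list passed with fry alone (adjusted p = 0.0341). Acute phase genes had a mean of 2.22 (1.74 and 2.71 by chip; adjusted p = 9.74e-12), with 10 of 18 higher and 0 lower (13 adjusted over the list alone). Serpina3n rose by 3.91 ± 0.17. Glucocorticoid response genes had a mean of 1.58 (1.49 and 1.66 by chip; adjusted p = 6.81e-11), with 9 of 19 higher and 0 lower (15 adjusted over the list alone). Fkbp5 rose by 2.07 ± 0.27 and Angptl4 by 1.86 ± 0.25 (another detected probe 0.84). Neutrophil markers had a mean of 1.47 (1.76 and 1.18 by chip; adjusted p = 7.03e-09, and adjusted p = 0.192 with an estimated correlation), with 9 of 22 higher and 0 lower (12 adjusted over the list alone). Fpr2 rose by 3.02 ± 0.25 and its relative Fpr1 by 2.10 ± 0.25.

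Anti-inflammatory regulators had 5 of 21 higher and 0 lower (13 adjusted over the list alone; mean 1.38, 0.85 and 1.92 by chip; adjusted p = 8.10e-07, and adjusted p = 0.279 with an estimated correlation). Il1r2 rose by 3.77 ± 0.38, Socs3 by 3.72 ± 0.52 and Il18bp by 1.06 ± 0.18. Chemokines had 4 of 21 higher and 2 lower (12 and 3 adjusted over the list alone; mean 1.51, 0.50 and 2.51 by chip; adjusted p = 0.00219). Their adjusted p was 0.455 with an estimated correlation, 0.0558 with fry and 0.280 on BeadChip 1 alone, and without CLP/MSC replicate 7 their mean was 0.98. Cxcl12 rose by 1.43 ± 0.11 (other detected probes 0.39 and -0.02), Ccl9 by 2.01 ± 0.33 and Cxcl13 by 1.29 ± 0.22. Toll-like receptor and NF-kB genes had 7 of 36 higher and 1 lower (10 and 2 adjusted over the list alone; mean 0.42, 0.28 and 0.57 by chip; adjusted p = 0.0117, and adjusted p = 0.352 with an estimated correlation). Bcl3 rose by 1.46 ± 0.25 and Tlr2, a receptor for bacterial lipoproteins, by 1.32 ± 0.29, a call lost without any 1 sham array or CLP/MSC replicate 7 (adjusted p from 0.0548 to 0.0605). Irak3, an inhibitor of this signalling, rose by 1.24 ± 0.28, a call lost without any 1 sham array or CLP/MSC replicate 8 (adjusted p from 0.0511 to 0.0693). Immediate-early genes had 2 of 17 higher and 0 lower (5 and 1 adjusted over the list alone; mean 0.73, 0.26 and 1.19 by chip; adjusted p = 0.0162). The adjusted p of this list was 0.490 with an estimated correlation and 0.0617 without CLP/MSC replicate 7 (mean 0.47). Myc rose by 1.57 ± 0.32 and Ier3 by 2.76 ± 0.71, which was not called without any 1 sham array or CLP/MSC replicate 7 or 8 (adjusted p from 0.0796 to 0.0932). Dusp1 did not pass (1.93 ± 0.58, adjusted p = 0.0621).

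NK cell markers had 9 of 16 lower and 0 higher (11 adjusted over the list alone; mean -1.19, -0.997 and -1.38 by chip; adjusted p = 7.03e-09). Xcl1 fell by 1.94 (SE 0.26), Klra7 fell by 1.71 (SE 0.25) and Klra1 fell by 1.80 (SE 0.16). B cell markers had 7 of 24 lower and 0 higher (18 adjusted over the list alone; mean -1.01, -0.62 and -1.40 by chip; adjusted p = 1.01e-08, and adjusted p = 0.292 with an estimated correlation). Cd1d1 fell by 1.36 (SE 0.16). T cell markers had 7 of 26 lower and 0 higher (17 and 1 adjusted over the list alone; mean -0.66, -0.44 and -0.89 by chip; adjusted p = 1.78e-06, and adjusted p = 0.279 with an estimated correlation). Cd2 fell by 1.04 (SE 0.19), Cd247 fell by 1.01 (SE 0.20; another detected probe -0.54) and the transcription factor Ets1 fell by 0.64 (SE 0.13; other probes -0.58 and -0.24), a call lost without sham replicate 1 (adjusted p = 0.0547). MHC class II genes had 8 of 15 lower and 0 higher (10 and 1 adjusted over the list alone; mean -0.70, -0.59 and -0.81 by chip; adjusted p = 0.000193, and adjusted p = 0.221 with an estimated correlation). H2-Aa fell by 0.87 (SE 0.12), H2-Oa fell by 1.26 (SE 0.23) and H2-Ab1 fell by 0.81 (SE 0.18). The call for H2-Ab1 was lost without any 1 sham array or CLP/MSC replicate 7 (adjusted p from 0.0514 to 0.0621). Dendritic cell markers had 7 of 15 lower and 0 higher (7 and 2 adjusted over the list alone; mean -0.79, -0.88 and -0.69 by chip; adjusted p = 0.000323, and adjusted p = 0.119 with an estimated correlation). Cd209a, Clec4a4 and Xcr1 were undetected in CLP/MSC spleens, at least 2.11-fold, 3.27-fold and 1.84-fold lower.

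The metallothionein, iron and haem list had 7 of 16 members higher and 0 lower (7 and 2 adjusted over the list alone; mean 0.64, 0.69 and 0.59 by chip; adjusted p = 0.00524, and adjusted p = 0.0820 with an estimated correlation). Ceruloplasmin, Cp, rose by 2.004 ± 0.19 (from 0.46 to 2.79 in other detected probes) and the metallothionein Mt1 by 1.99 ± 0.29. Bacterial killing genes had 7 of 25 higher and 1 lower (7 and 1 adjusted over the list alone; mean 0.62, 0.69 and 0.54 by chip; adjusted p = 0.0200). Their adjusted p was 0.350 with an estimated correlation, 0.0685 without CLP/MSC replicate 5 and 0.0510 with median scaling. Hmox1, which breaks down haem, rose by 1.26 ± 0.23 and the phagosomal metal transporter Slc11a1 by 1.01 ± 0.15. Endothelial markers had 3 of 20 higher and 0 lower (5 adjusted over the list alone; mean 0.40, 0.22 and 0.57 by chip; adjusted p = 0.00976, and adjusted p = 0.232 with an estimated correlation). Robo4 rose by 1.08 ± 0.27, a call lost without any 1 sham array or CLP/MSC replicate 7 or 8 (adjusted p from 0.0654 to 0.0988). The adhesion molecule Madcam1 rose by 0.77 ± 0.21, a call lost without any 1 sham or CLP/MSC array or without CLP/saline replicate 10 (adjusted p from 0.0540 to 0.117). Flt4 passed (adjusted p = 0.0250) but was undetected in every sham spleen, close to background elsewhere, and not called without sham replicate 1, 3 or 5 or CLP/MSC replicate 8 (adjusted p from 0.0612 to 0.0799). Glycolysis and hypoxia genes had 4 of 28 higher and 1 lower (4 and 1 adjusted over the list alone; mean 0.20, 0.25 and 0.15 by chip; adjusted p = 0.0200). Their adjusted p was 0.232 with an estimated correlation and 0.0696 without CLP/MSC replicate 5. The glycolytic enzymes Pfkp and Pkm rose by 0.76 ± 0.16 and 0.66 ± 0.12, and probes the file names Pkm2, for the same enzyme, by 0.93 ± 0.11. That enzyme entered the list under both names, so it counts as more than 1 of the 28 members.

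Oxidative phosphorylation genes had 1 of 37 lower (0 adjusted over the list alone; mean -0.19, -0.09 and -0.30 by chip; adjusted p = 0.00446). Their adjusted p was 0.455 with an estimated correlation and 0.0510 with median scaling. Cox7a2 fell by 0.59 (SE 0.16), a call lost without any 1 sham or CLP/MSC array (adjusted p from 0.0505 to 0.112). Atp5h (-0.41 ± 0.13, adjusted p = 0.0765) and Ndufa1 (-0.39 ± 0.13, adjusted p = 0.0964) did not pass. Type I interferon response genes passed with a mean of 0.79 that was -0.15 on BeadChip 1 and 1.72 on BeadChip 2 (1 of 32 higher and 1 lower, 1 and 1 adjusted over the list alone; adjusted p = 0.0237). The adjusted p was 0.711 with an estimated correlation, and without CLP/MSC replicate 7 the mean was 0.14 and the adjusted p 0.983. Lgals3bp rose by 1.11 ± 0.18, while Oas2 (1.75 ± 0.77, adjusted p = 0.176) and Irf7 (1.30 ± 0.69, adjusted p = 0.253) did not pass.

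Mesothelial markers had 3 of 7 lower (3 adjusted over the list alone; mean -0.87, -0.37 and -1.37 by chip; adjusted p = 0.0401, and adjusted p = 0.279 with an estimated correlation). That list did not pass without sham replicate 3 or 4, CLP/saline replicate 3 or CLP/MSC replicate 5 or 7 (adjusted p from 0.0537 to 0.0838). Gpm6a was undetected in CLP/MSC spleens, at least 2.47-fold lower, and the uroplakins Upk3b and Upk1b had log2 changes of -2.31 ± 0.57 and -1.98 ± 0.48. These calls were lost without sham replicate 3, 4 or 5, for Upk3b also without CLP/MSC replicate 4, 5 or 8 and for Upk1b without 5 or 7 (adjusted p from 0.0527 to 0.0872). Exocrine pancreas genes had a mean of -2.61, 1.96 on BeadChip 1 and -7.18 on BeadChip 2 (0 of 28 higher or lower, 0 adjusted over the list alone; adjusted p = 0.0200, and adjusted p = 0.713 with an estimated correlation). That list did not pass without sham replicate 3 or 5 or CLP/MSC replicate 7 or 8 (means -1.72, -1.74, -1.20 and -1.24; adjusted p from 0.124 to 0.221). Without CLP/MSC replicate 5 its mean was -4.11, and it turned to 1.196 with array weights and 0.59 with the animal number as a block. Amy2a5 (-3.20 ± 1.71), Rnase1 (-4.62 ± 2.50) and Ctrc (-2.32 ± 1.38) did not pass. Erythroid genes (mean -0.03, -0.99 and 0.92 by chip; adjusted p = 0.966) and cell cycle genes (mean -0.08, -0.54 and 0.38 by chip; adjusted p = 0.536) did not pass against sham.

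Lcn2, Saa3, Serpina3n, Fpr2, Il10 and Fcer2a were among 1034 genes called in both comparisons with sham, 545 higher in both, 489 lower in both and 0 opposite. They made up 84.0% of the genes called in CLP/MSC spleens. Independent lists of these sizes would share 50.3 higher and 39.7 lower genes. Simulated unchanged groups against the same sham arrays shared 0. Such groups hold no change to call, so that 0 does not measure what the common sham arrays add. With the sham arrays split so that each comparison had its own 2, 215 genes were shared on average (193 to 250 over the splits), of 434 and 309 called. The covariance of both effects across genes was 0.368, against 0.0608 in simulated unchanged groups, a difference of 0.307, and 0.338 with split sham arrays. Their correlation was 0.916, against 0.501 simulated and 0.793 with split arrays. The simulation gave each gene the same spread in all groups, but the median SD was 0.167 in sham and 0.320 in CLP/saline spleens. Its values may therefore overstate what shared sham arrays add.

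Whether MSCs turned back the changes that CLP made was tested across genes. Limma called 0 genes as changed by CLP and moved the opposite way by MSCs, as it called 0 genes between CLP/MSC and CLP/saline. Of all tested genes, 613 had an unadjusted p under 0.05 in that comparison. With all 4 CLP/saline arrays in both comparisons the covariance of the CLP and MSC effects was -0.0751, against -0.0609 in simulated unchanged groups. The simulation gave each gene the same spread in all groups, but the median SD was 0.167 in sham and 0.320 in CLP/saline spleens. It may understate what shared CLP/saline arrays add, so the gap between these covariances is no evidence of a reversal. With the CLP/saline arrays split over the 2 comparisons the covariance averaged -0.00139 over 6 assignments (-0.0870 to 0.122). An exact two-sided permutation test of it over 70 labellings gave p = 0.986. Of the 2255 genes called after CLP, 1776 (78.8%) had a CLP/MSC mean nearer to sham than the CLP/saline mean. Of the 1231 genes called in CLP/MSC spleens, 650 (52.8%) had a CLP/saline mean nearer to sham. Genes picked for lying far from sham in one group tend by selection to lie nearer in another, and neither share was tested.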

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

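Tests of study group and of BeadChip as the cause of the exocrine pancreas levels, both tests on the cytokine spread, and the permutation over animals of the erythroid excess were chosen after the results were seen. The other tests were chosen beforehand.

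For each group of 4 arrays the gap of the highest or lowest array to its nearest neighbour was divided by the group's range (Dixon's ratio). Of 435 values, 21 (4.83%) lay above the critical value. Chance gives about 1 in 20, so the flagged set as a whole is no larger than chance gives. Tnf was flagged in every group, at 0.917 in sham replicate 1, 0.978 in CLP/saline replicate 2 and 0.869 in CLP/MSC replicate 7. Its sham log2 signals spanned only 7.12 to 7.52. In CLP/saline replicate 2 and CLP/MSC replicate 7 its log2 signal was 10.10 and 10.53, and it was at most 7.81 in the other CLP arrays. CLP/MSC replicate 7 was also highest for Oas2, an interferon-induced enzyme (0.868; log2 signal 11.81 against 8.71 next), and for the alternative activation list (0.940), and lowest for Cd3d (0.845). CLP/saline replicate 10 was highest for Il18bp (0.904) and Ets1 (0.937) and lowest for Tap2 (0.853) and for the dendritic cell list (0.959). Replicate 3 of that group was lowest for Tirap (0.842) and Gfi1 (0.909), replicate 2 was lowest for the megakaryocyte and platelet list (0.885) and replicate 8 highest for Cox7a2 (0.931). Sham replicate 1 was highest for Clec9a (0.880), Fpr2 (0.885) and the apoptosis list (0.888) and lowest for Amy2a5 (0.82901). Sham replicate 5 was highest for the NK cell list (0.941) and lowest for the complement list (0.968), and sham replicate 4 was lowest for the splenic macrophage list (0.847).

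The first pattern is the range of exocrine pancreas genes between spleens. Islet genes, of which 9 of 25 were tested, ordered 56 of the 66 pairs of arrays as the exocrine genes did (one-sided permutation p = 0.00044, 100000 permutations), so pancreatic tissue collected with the spleen may be the source. The islet mean was highest in sham replicates 3 and 5 and CLP/saline replicate 2 (7.45, 7.40 and 6.98), but in CLP/MSC replicates 4, 5, 7 and 8 it was 5.77, 5.88, 5.77 and 5.75 beside exocrine means of 13.39, 14.07, 5.35 and 5.47, so islet genes do not trace the source there. A share of 0.916 of the variance lay within groups, which argues against the study group as the whole cause, and sham arrays of the same chip differed by 6.19 and 4.42, which argues against the BeadChip as the whole cause in sham spleens. In CLP spleens every array of BeadChip 1 lay above every array of BeadChip 2, by at least 4.88. Sham arrays read 8.68 and 14.86 on BeadChip 1 and 10.38 and 14.80 on BeadChip 2, which argues against a chip effect common to all groups. In the CLP spleens, tissue content and a chip effect confined to them cannot be told apart.

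The second pattern is the higher erythroid list in CLP/MSC than in CLP/saline spleens. Erythroid genes move together between animals: with their correlation estimated the adjusted p was 0.999 (mean difference 0.88, all 27 members above 0), so differences between single animals may account for it. Less pancreatic tissue in the CLP/MSC spleens would raise other splenic cell types alike and cannot be told apart: erythroid genes exceeded 50 B and T cell genes by 0.854 ± 0.721 (SE over animals; exact two-sided permutation p = 0.314), by -0.14 and 1.84 within chips, and the bound set beforehand, on an SE over genes (0.0908), was wrong for genes that move together. A chip effect shared by all groups cancels from this mean, since each chip held 2 arrays of each group (0.879 with the chip as a block, a value that the design fixes), but a chip effect that differs between groups cannot be told apart from differences between animals (0.17 and 1.59 within chips). An effect of the infused cells stays open.

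The third pattern is the spread of inflammatory genes between CLP spleens. The cytokine list mean had an SD of 0.05 in sham, 0.91 in CLP/saline and 1.05 in CLP/MSC spleens, and 78.2% of all genes had a larger SD in CLP/saline than in sham spleens (74.5% in CLP/MSC). On BeadChip 1 alone the CLP/saline arrays differed by 2.03, and on BeadChip 2 by 0.419, which argues against the BeadChip as the whole cause. Pancreatic tissue as the whole cause is also argued against, since those arrays of BeadChip 1, 2.03 apart in cytokines, were only 0.894 apart in exocrine genes, and CLP/MSC replicates 7 and 8 were 1.69 and 0.12 apart. Differing severity of the infection between animals could account for it and was not tested.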

How the results depend on the processing

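Fits to 1 BeadChip alone, with an exocrine pancreas covariate and without exocrine probes were chosen after seeing the data. No array left out, and no other alternative run, gave a called gene between CLP/MSC and CLP/saline. Of the named genes' values under the alternatives, 7976 kept direction and side of the threshold, 625 lost the call and 100 gained it. A further 69 changed direction without passing in either fit, and 0 changed direction with a pass in either fit. Only lists called in the main fit were followed, so gained list calls are not counted. Of their values 1136 kept, 102 lost the call and 7 reversed. The cause was not tested, except that stricter thresholds call fewer genes by construction. Signal over background limits Nos2, which had no probe past the detection filter. No probe carried the name Ly6g, so that gene was not measured under its name.

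Genes changed between CLP/saline and sham (2255) were 4812 with array weights, 457 with the animal number as a block, 972 at 2-fold or more, 499 and 3980 at adjusted p under 0.01 and 0.1, and 16 and 1027 on BeadChip 1 and 2 alone. With 1 array left out they were 879 to 4312. Genes changed between CLP/MSC and sham (1231) were 3452 with array weights, 573 at 2-fold or more, and 343 and 2206 at adjusted p under 0.01 and 0.1. They were 770 with chip block and exocrine covariate, and 32 and 1713 on BeadChip 1 and 2 alone. With 1 array left out they were 523 to 1737. The same animal number occurs in fewer than 3 pairs per comparison, and the labels do not say that it pairs animals.

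Lists changed between CLP/saline and sham (15) were 23 with no detection filter, 24 with the animal number as a block and 2 with an estimated correlation. Between CLP/MSC and CLP/saline (4) they were 7 with array weights, 0 with an estimated correlation, 0 with fry, 8 and 9 on BeadChip 1 and 2 alone and 3 to 9 with 1 array left out. Between CLP/MSC and sham (20) they were 3 with an estimated correlation. The covariance of the CLP and MSC effects with split CLP/saline arrays (-0.00139) was 0.00126 with no background correction, 0.00111 with an offset of 50, 0.000393 in the authors' values and -0.119 to 0.0543 with 1 array left out.

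The cell cycle list reversed between CLP/MSC and CLP/saline on BeadChip 1 alone (-0.0823). Against sham, the exocrine list of CLP/MSC spleens reversed with array weights (1.196), the animal number as a block (0.59) and on BeadChip 1 alone (1.96). The type I interferon list reversed there with the animal number as a block (-0.0843) and on BeadChip 1 alone (-0.15), and had a mean of 0.0423 with the opposite camera direction under array weights. The erythroid list between CLP/MSC and CLP/saline had adjusted p values from 2.89e-21 to 0.999 over its alternatives.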

Other observations

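The values of the interferon list by array, and of the genes set beside the splits, were chosen after they were seen. The other values and the splits were planned. Macrophage genes of the spleen moved apart. Marco, a scavenger receptor of marginal zone macrophages, rose by 2.18 ± 0.20 after CLP (adjusted p = 7.04e-05) and by 2.35 ± 0.20 in CLP/MSC against sham spleens (adjusted p = 4.73e-05), in all 4 arrays above all sham arrays. Spic, a transcription factor of red pulp macrophages, rose by 1.05 ± 0.19 after CLP, and its difference was 1.11 in CLP/MSC against sham spleens. Cd209b, a lectin of marginal zone macrophages, had a difference of -1.48 after CLP and fell by 2.02 (SE 0.33) in CLP/MSC against sham spleens. The splenic macrophage list had 2 of 18 members higher and 5 lower after CLP (4 and 5 adjusted over the list alone) and did not pass (mean -0.14, -0.28 and 0.01 by chip; adjusted p = 0.876).

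Neutrophil precursor genes had 4 of 11 members higher and 0 lower after CLP (4 adjusted over the list alone; mean 0.63, 0.29 and 0.97 by chip). The list passed with the chip as a block (adjusted p = 0.0484) but not without it (adjusted p = 0.0574, and adjusted p = 0.495 with an estimated correlation). Hdc, which makes histamine, rose by 2.53 ± 0.42 and the transcription factor Gfi1 by 0.82 ± 0.16.

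Interferon-induced genes differed between spleens of one group. The type I interferon list lay 1.77, 0.19, 1.15 and -0.41 from the sham mean in CLP/saline replicates 2, 3, 8 and 10, and -0.04, -0.13, 2.72 and 0.59 in CLP/MSC replicates 4, 5, 7 and 8. Between CLP/MSC and CLP/saline its mean difference was -1.06 on BeadChip 1 and 1.28 on BeadChip 2 (0.11 over both; adjusted p = 0.376).

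Other splits of the 8 arrays of each comparison, 35 in all with the real one, were tested. For genes changed between CLP/saline and sham only 1 split, the real one, gave as many (2255, highest other 42). Between CLP/MSC and sham it was also 1 (1231, highest other 0). This argues against chance for both counts but does not exclude it, since 1 of 35 is the smallest share the test can give. Chance cannot be excluded for the list counts, since 11 splits gave at least 15 lists between CLP/saline and sham (highest other 19) and 5 gave at least 20 between CLP/MSC and sham (highest other 22). Between CLP/MSC and CLP/saline limma called 0 genes (613 at an unadjusted p under 0.05), so all 35 splits give as many by construction and say nothing about that count. For its 4 lists chance cannot be excluded, since 35 splits gave at least as many (highest other 20). The splits were not kept balanced over the BeadChips, so some of those in this comparison also separate the chips. The highest other split there called 5031 genes, with CLP/saline replicates 2 and 8 and CLP/MSC replicates 7 and 8 against the rest, and the split by BeadChip called 524 genes and 7 lists. A split that calls so many genes points to a structure of the samples across both groups. Among CLP spleens, CLP/saline replicates 2 and 8 and CLP/MSC replicates 7 and 8 had the highest log2 signals of Il6. These were 12.46, 8.98, 12.23 and 8.47, and at most 5.80 in the others. Isg15 also set them apart (12.53, 12.10, 14.72 and 12.14, others at most 10.28), but Tnf and Il1b did not. The cause was not tested. With the chip as a block the real split still gave 0 genes.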
